A study of Mus musculus with 2 samples.

How the data were processed

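Osteoclast precursors from mouse bone marrow were cultured with M-CSF or with M-CSF + RANKL, and their RNA was hybridised to Illumina bead arrays. Per the labels, each of the 2 samples is the mean of 3 biological replicates that were run on separate arrays. What made the replicates separate (animals, sorts or cultures) is not given in the sources used here, nor whether those of the 2 groups were matched, so p-values measure the spread between these replicates only. The authors deposited a normalized intensity on a linear scale for each array gene and group, with the SD between arrays in the same unit. The normalization method, the software and the array version are not given in the sources used here. The deposited table also holds a detection p-value per gene and group, and a ratio of the 2 means that the authors computed. The header of that ratio names M-CSF over RANKL, whereas in all 31492 array genes its value equals RANKL over M-CSF within a relative tolerance of 1e-06. It was not used further. The series' value table holds the same means in all 31492 array genes. Means ran from 105 to 71023 with M-CSF alone and from 98.5 to 70773 with RANKL, with medians of 158 in both. Background was not set to 0, since genes with a detection p of 0.01 or more had median signals of 145 in both groups, so folds of dim genes are understated. For 24796 genes with M-CSF alone and 24696 with RANKL the detection p moves in equal steps, as a rank among control beads would. For the remaining genes it does not follow the signal, and means as high as 46539 carry a detection p of 0.01 or more.

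Array names were matched to current symbols with the RefSeq gene table of assembly GRCm38.p6, used for names only. Of 31492 names, 13430 matched a current symbol, 8111 a single synonym, 168 the synonym of several genes and 9756 none, and 27 had been altered by spreadsheet software. No coordinates are printed, because the array's build is not named. Where several array genes share a symbol (1808 symbols), the brightest over both groups stands for it in the named genes and lists. Among named genes, Clec5a and Pde4dip have further array genes, all called in the same direction. Cross-hybridisation between close paralogs, such as Lyz1 and Lyz2 or Ctla2a and Ctla2b, was not examined.

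The unit of the values and the lack of single arrays set the test, as fixed before the data were examined. The effect is the log2 ratio of the group means. The variance of each log2 mean was taken from the deposited SD by the delta method, the 2 group variances were pooled on 4 degrees of freedom, and the pooled variance was moderated across genes with limma 3.58.1 (squeezeVar with an intensity trend, prior degrees of freedom 7.49) in R 4.3.3. Tests are two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Tested genes had a detection p under 0.01 in at least 1 group. The lowest signals detected by a stepped detection p, 198 with M-CSF alone and 196 with RANKL, served as floors. They were chosen after seeing the data, in place of the lowest detected signals of any gene, 164 and 160, since detection p-values outside the steps do not follow the signal. Where a group was not detected and read under its floor, the fold is the brighter mean over that floor and is a lower bound. Fosl2, Oasl2, Prf1, Rhou and Rnase4 read at or above the floor in a group not detected, and their folds are plain ratios. Counts by fold and list medians use the measured signals unless the floor is named. The procedure was tested on simulated data with 11012 genes, of which 200 were changed. It recovered 10 of 50 at 1.25-fold, 32 of 50 at 1.5-fold, 48 of 50 at 2-fold and 50 of 50 at 4-fold. There were 6 false calls among 146. In the real data 57.8% of tested genes were called, a far larger share than was changed in the simulation. The adjusted threshold depends on that share, so these recovery rates do not carry over to the real data. On the real table, 13273 genes with stepped detection p-values of 0.1 or more in both groups were tested the same way. Of these, 709 (5.34%, 95% exact binomial interval 4.97 to 5.74) had an unadjusted p under 0.05 in limma, and 0 passed adjustment. The interval treats the genes as independent although they were read on the same arrays, so it may be too narrow. Such genes were chosen for reading at background in both groups and were fitted apart. This rate therefore does not describe false calls among detected genes.

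Gene lists (27) were fixed before the data were examined. They cover osteoclast resorption, cell fusion, V-ATPase subunits, RANK signalling, ITAM signalling, regulators listed as repressors of osteoclast formation, and monocyte and macrophage genes. They also cover type I interferon response, antigen presentation, chemokines and cytokines, coupling factors, cell cycle and its inhibitors, mitochondria and glycolysis. The rest are cholesterol synthesis, cytoskeleton, 8 sets of markers of other cell types, housekeeping and stress. Each list was described by its called members, its median log2 fold and limma's cameraPR. The latter used a preset correlation of 0.01, adjusted over the 24 lists with at least 3 tested genes. Since 57.8% of tested genes were called, nearly equally in the 2 directions, counts of called members are to be read against that share. Each median was also placed among 10000 random lists of the same size, matched on mean expression. Some lists that did not pass in cameraPR lay low there. Their percentiles were 0.18 (megakaryocyte), 0.62 (ITAM), 1.055 (cholesterol), 1.63 (progenitor) and 2.72 (antigen presentation). Adjusted over the list alone, the counts were the same except for 29 lower in the macrophage list, 39 lower in the cell cycle list, and 1 higher beside 1 lower in the stromal list. An estimated correlation needs the single arrays; with the preset raised to 0.05, 10 of the 11 called lists still passed. Of the members, the chemokine list shares 11 with other lists, the antigen presentation list 6, and the resorption, coupling and housekeeping lists 4 each. In the macrophage, interferon and cell cycle lists, 0 members were higher with RANKL at an unadjusted limma p under 0.05 as well. With undetected groups set to the floor, list medians moved by at most 0.12, except for the megakaryocyte list, from −0.68 to −0.25.

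Genes named in the text were chosen by a rule written before the data were examined. It takes 17 fixed genes, the 10 largest rises and 10 largest falls by log2 fold among called genes with a current symbol and a brighter group above the median of 818, and in each list up to 4 called members with the largest change. Of the genes under this rule, 3 are not reported here. Other genes are marked as named after their values were seen. Alternatives covered the filter, the variance model, the scale, an offset of 16, centring, quantile normalization of the group means, the source table, the array gene per symbol and the camera correlation. Added after seeing the data were a filter on signal in place of detection p, subtraction of background (floored at 16) and doubled SDs. Leaving out replicates, regrouping them and fitting pairs were not possible from group means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.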

Results

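Gene expression was measured on Illumina bead arrays in mouse osteoclast precursors, the bone marrow cells from which osteoclasts form. The cells came from C57BL/6 mice of 8 weeks and were sorted as negative for the T cell marker CD3 and the B cell marker CD45R, low or negative for the myeloid integrin CD11b, and positive for CD115, the M-CSF receptor. They were cultured for 3 days in 1 of 2 ways. Control cultures received macrophage colony-stimulating factor (M-CSF, 30 ng/ml), which keeps monocytes and macrophages alive and dividing. The others received M-CSF together with RANKL (both at 30 ng/ml), the cytokine that starts osteoclast formation. RNA was taken from the adherent cells. Each group stands for 3 biological replicates, each on its own array, and the deposited table gives the mean, the SD and a detection p of each of 31492 array genes in each group. Signals are linear intensities with background at about 145. The median SD was 6.89% of the mean with M-CSF alone and 6.78% with RANKL. At a detection p under 0.01, 10084 genes were detected with M-CSF alone and 10198 with RANKL. Below, values after a gene's name are the authors' means ± SD over the 3 replicates, and a fold is the ratio of these means. Where the dimmer group was not detected and read under the floor, 198 with M-CSF alone or 196 with RANKL, the fold is a lower bound, written "at least". The number of arrays, 3 per group, limits the precision.

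The comparison asks which genes change when RANKL is added to M-CSF. RANKL changed a large part of the transcriptome. Among genes eligible to be named and detected in both groups, the largest rises by log2 fold were those of Mmp9, Ctsk and Scin, and the largest fall that of C1qc. Mmp9 and Ctsk are not ordered here, since Ctsk with RANKL lies near the highest signal of the array. Genes not detected in a group have only a lower bound and so no exact rank, but some bounds exceed these folds. The rises of Slc9b2 (at least 146-fold), F2r (at least 142-fold) and Mt3 (at least 97.1-fold) were larger than that of Scin (92.7-fold). The fall of Fcrls (at least 77.4-fold) was larger than that of C1qc (56.5-fold). Of 11012 genes detected in at least 1 group, 6369 differed at an adjusted p under 0.05 by a limma moderated test, 3179 higher and 3190 lower with RANKL. The change was at least 2-fold for 1532 of them, 760 higher and 772 lower, and at least 10-fold for 59 higher and 39 lower. With undetected groups set to the floor, 719 higher and 754 lower genes changed at least 2-fold, and 52 and 38 at least 10-fold. No 2-fold difference missed the threshold, and the largest adjusted p among the 1532 was 0.00168 in limma. The median size of a called change was 0.59 on the log2 scale, against a median standard error of 0.10 over all tested genes. With both SDs doubled, a setting chosen after seeing the data, 3054 genes were called, and with a test of each gene on the linear means without moderation 3868 were called. After subtraction of the background signal, also chosen after seeing the data, 2759 genes changed at least 2-fold, because background compresses the folds of dim genes. Of 105 tested genes under the naming rule, 46 then had a fold more than 1.5 times larger, and 0 a fold that much smaller.

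Genes of bone resorption rose. Mmp9, a matrix metalloproteinase, went from 198 ± 19.2 to 56537 ± 8772, a 286-fold rise (log2 8.16 ± 0.12 SE). Ctsk, cathepsin K, the protease that digests bone collagen, went from 302 ± 119 to 67578 ± 1306, a 224-fold rise (log2 7.81 ± 0.21 SE), above 85% of the highest mean in that group, 70773, so the fold is understated if the probe saturates there. After subtraction of background the log2 folds were 10.06 for Mmp9 and 8.75 for Ctsk. Slc9b2, a sodium/proton exchanger of osteoclasts listed on the array under an older name, rose at least 146-fold, and Oscar, an immunoreceptor of osteoclasts that binds collagen, at least 48.2-fold. Acp5, tartrate-resistant acid phosphatase and the standard stain for osteoclasts, rose at least 10.4-fold, to 2051 ± 322. Itgb3, the beta3 integrin chain, rose at least 1.27-fold, to 251 ± 49.6 (adjusted p = 0.00104, limma). Among 26 tested genes of the resorption list, 18 rose, 6 fell and 2 did not pass, with a median log2 fold of 1.27 (cameraPR adjusted p = 4.22e-18). The 6 that fell are Ctsb, Ctsd, Ctsl, Acp2, Rab27a and Ptk2b, named after their values were seen. The first 4 encode enzymes found in the lysosomes of many cell types. Calcr, the calcitonin receptor, read 141 ± 5.26 with M-CSF alone and 396 ± 102 with RANKL. It was left out of the test because its detection p with RANKL was 0.0168.

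**Figure D1:**
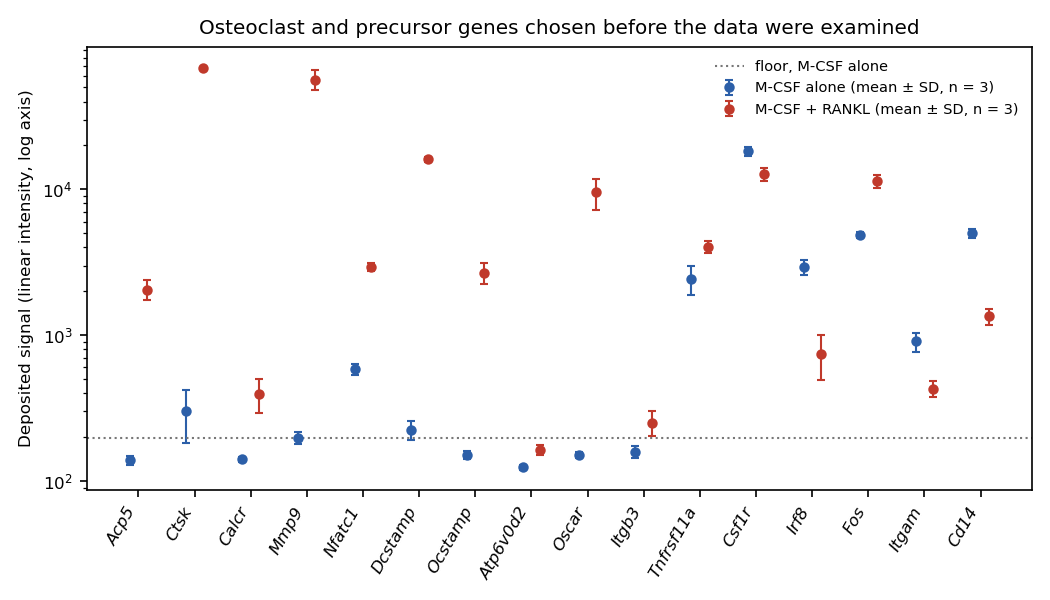
Deposited signal (linear intensity, logarithmic axis) of 16 genes chosen before the data were examined, with M-CSF alone (blue) and M-CSF + RANKL (red); points are means and bars the SD over 3 replicates, and the dotted line is the floor with M-CSF alone, 198. Ctsk lies at 302 in the control and at 67578 with RANKL, whereas Atp6v0d2 lies below the dotted line in both groups.

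Fusion of precursors makes the multinucleated osteoclast, and 4 membrane proteins linked to it rose. Dcstamp, the dendritic cell-specific transmembrane protein that fusion requires, went from 224 ± 34.1 to 16037 ± 553, a 71.5-fold rise (log2 6.16 ± 0.12 SE, or 7.65 after subtraction of background). Ocstamp, its partner, rose at least 13.6-fold, the receptor tyrosine kinase Mst1r at least 32.0-fold, and Cd200 from under the floor to 2574. The list of 13 tested fusion genes was split, with 6 higher, 4 lower and 3 not passing. Its median was only 0.19 (cameraPR adjusted p = 4.97e-05), at percentile 85.2 of random lists matched on mean expression. With a filter on signal in place of detection, chosen after seeing the data, the median was 0.30. The falls included the tetraspanin Cd81, from 27508 to 4373, and the metalloproteinase Adam8, from 4576 to 759, both named after their values were seen. Atp6v0d2, a proton pump subunit also tied to fusion, read 124 ± 4.43 and 163 ± 12.1. It was detected in neither group, so no fold is given.

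The signalling genes downstream of RANK, the receptor of RANKL, were mostly higher. Nfatc1, the transcription factor that directs osteoclast formation, rose 5.05-fold from 581 ± 48.0 to 2936 ± 195 (log2 2.34 ± 0.10 SE). Fos, which acts upstream of it, rose 2.35-fold to 11406 ± 1148. Larger rises were seen for the AP-1 family member Jdp2 (log2 4.06 ± 0.09 SE, 1145 to 19063), for the TNF receptor adaptor Traf1 (log2 3.90 ± 0.10 SE), and for Rcan1, an inhibitor of calcineurin (log2 2.95 ± 0.11 SE). Fosl2, another AP-1 member, rose 7.35-fold. Tnfrsf11a, which encodes RANK itself, rose 1.65-fold from 2433 ± 546 to 4024 ± 372 (adjusted p = 0.00111, limma). With both SDs doubled its adjusted p was 0.0888 and that of Itgb3 0.0861. Of 32 tested genes in this list, 21 rose, 7 fell and 4 did not pass (median 0.70, cameraPR adjusted p = 7.49e-07), and the median was 1.06 after subtraction of background and 0.35 with no filter on detection.

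Proton pumping and mitochondrial metabolism moved up as groups. The V-ATPase is the pump that acidifies lysosomes and the resorption pit, and 15 of its 17 tested subunits rose, 1 fell and 1 did not pass, with a median log2 fold of 1.23 (cameraPR adjusted p = 3.19e-08). Atp6v1d went from 7994 ± 609 to 32483 ± 1071, Atp6v1b2 from 18524 ± 1034 to 63129 ± 5536, and Atp6v0c from 286 ± 12.2 to 1066 ± 137. With RANKL, Atp6v1b2 lies above 85% of the highest mean in that group, so its fold is understated if the probe saturates there. The subunit that fell was Atp6v0a1, 1 of the alternative a subunits, which went from 3047 ± 374 to 554 ± 18.3 (log2 −2.46 ± 0.11 SE). Another a subunit, Tcirg1, which osteoclasts need for resorption, went from 4061 to 13156 and was named after its value was seen. For oxidative phosphorylation and mitochondria, 59 of 60 tested genes rose and 1 fell (median 0.80, cameraPR adjusted p = 1.75e-14). Ppargc1b, a coactivator that drives mitochondrial biogenesis, led the list with a 13.1-fold rise from 448 ± 47.3 to 5878 ± 518. The citric acid cycle enzymes Mdh2 and Idh3a rose 3.20-fold and 3.01-fold. The gene that fell was the transcription factor Nrf1, from 1476 to 1110, named after its value was seen. Glycolysis genes went both ways, with 8 higher, 3 lower and 6 of 17 not passing (median 0.21, or 0.09 with no filter, cameraPR adjusted p = 0.818). The lactate dehydrogenase subunit Ldhb rose 7.13-fold and the hexokinase Hk3 fell 4.63-fold, whereas Hk1 and the pyruvate dehydrogenase kinase Pdk1 rose by 0.70 and 0.69 on the log2 scale.

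**Figure D2:**
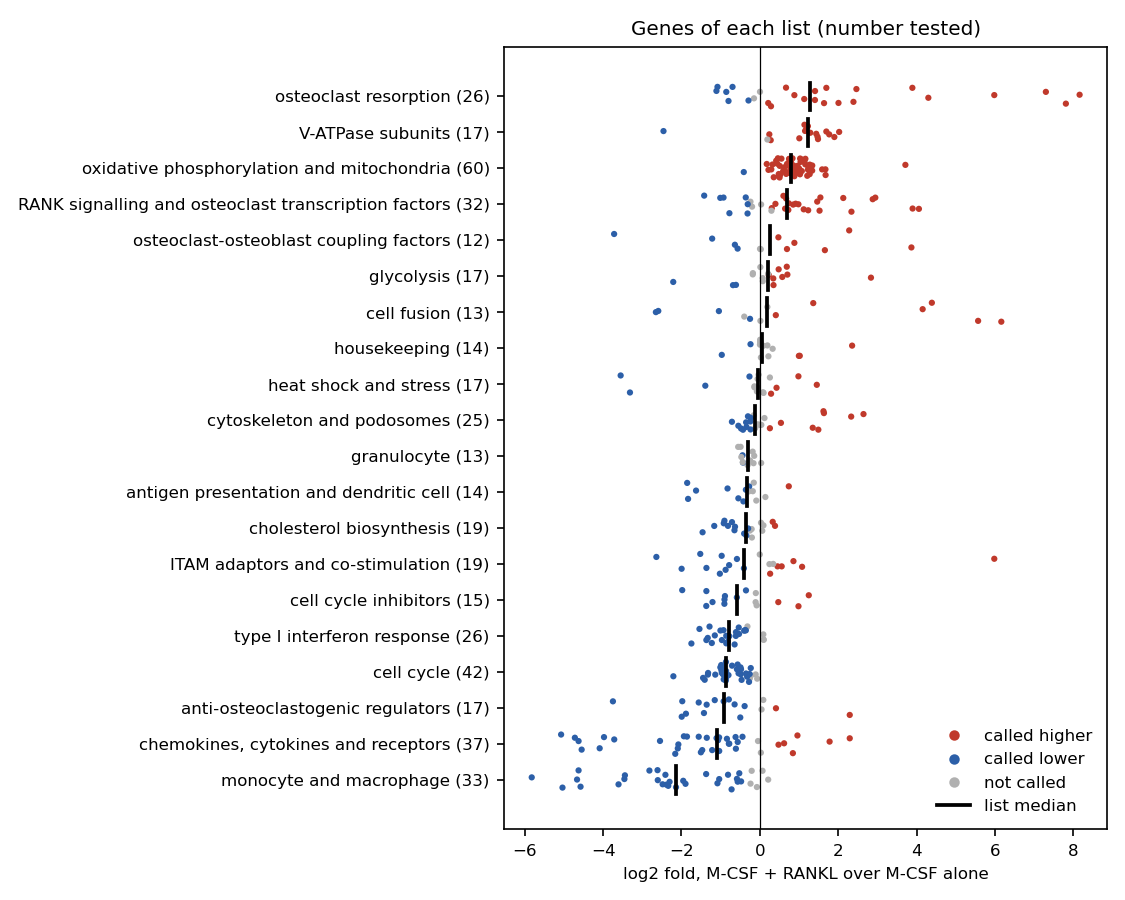
Log2 fold of M-CSF + RANKL over M-CSF alone for the tested genes of each list with at least 10 of them; each point is a gene, coloured red if called higher, blue if called lower and grey if not called, and the black bar is the list's median. The list medians run from −2.14 for monocyte and macrophage genes to 1.27 for resorption genes, and the genes of oxidative phosphorylation lie almost all to the right of 0.

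Genes that characterise monocytes and macrophages fell. None of the 33 tested rose, 28 fell and 5 did not pass, with a median log2 fold of −2.14 (cameraPR adjusted p = 7.32e-29). The chains of complement C1q, which macrophages secrete, fell steeply. C1qc went from 34802 ± 1505 to 616 ± 22.0 (56.5-fold lower), C1qb from 48975 ± 3199 to 1492 ± 151 (32.8-fold lower), and C1qa fell at least 24.7-fold. The fractalkine receptor Cx3cr1 fell 24.7-fold from 17015 ± 1980 to 689 ± 111. Cd14, the co-receptor for bacterial lipopolysaccharide, fell 3.73-fold to 1341 ± 175, and Itgam, the CD11b chain, fell 2.12-fold to 428 ± 53.0. Csf1r, the M-CSF receptor on which the cells were sorted, fell less, 1.44-fold from 18261 ± 1386 to 12688 ± 1294 (log2 −0.53 ± 0.09 SE). Cd68 and Lyz1 are also myeloid genes and were named after their values were seen. They read 35480 and 22272 with M-CSF alone and 33656 and 23345 with RANKL, differences that did not pass. The scavenger receptor relative Fcrls fell at least 77.4-fold from 15199 ± 1747. Large falls outside the lists were those of the organic anion transporter Slco2b1 (at least 38.2-fold), Ctla2b (at least 36.6-fold), the ribonuclease Rnase4 (37.1-fold) and the cholesterol 25-hydroxylase Ch25h (at least 18.4-fold).

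**Figure D3:**
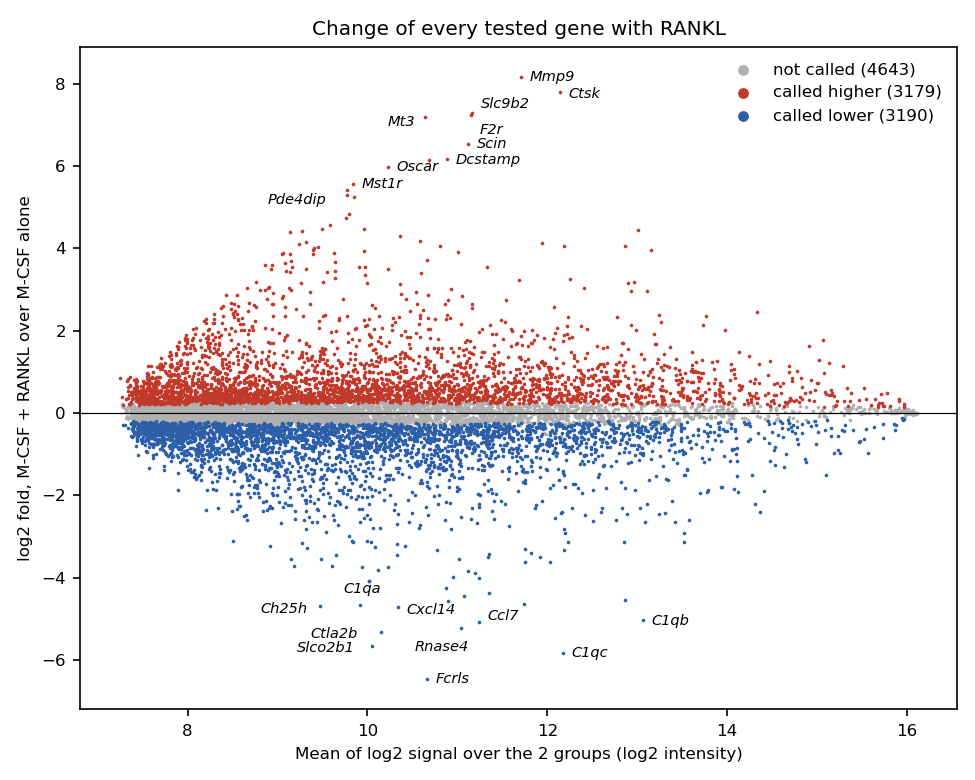
Log2 fold of M-CSF + RANKL over M-CSF alone against the mean log2 signal of the 2 groups for the 11012 tested genes, with genes called higher in red (3179), called lower in blue (3190) and not called in grey (4643). Labels mark the 10 largest measured rises and falls with a current gene symbol and a brighter group above 818. Mmp9 lies at 8.16 and C1qc at −5.82, both detected in the 2 groups, whereas genes not detected in a group are drawn at their measured signals and have no exact fold.

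Regulators listed as repressors of osteoclast formation were lower as a group, with 13 of 17 tested genes down, 2 up and 2 not passing (median −0.92, cameraPR adjusted p = 0.00054). The list was not checked member by member and may hold genes with other roles in osteoclast formation. The median was −1.68 after subtraction of background and −0.57 with no filter. The inhibitor of differentiation Id1 fell 13.4-fold from 4415 ± 231 to 328 ± 27.1, and its relative Id3 fell 3.98-fold. Irf8, a transcription factor of the monocyte lineage that blocks Nfatc1, fell 3.95-fold from 2940 ± 350 to 745 ± 252 (log2 −1.98 ± 0.20 SE). Il10, the anti-inflammatory cytokine, went the other way and rose at least 4.24-fold to 838 ± 101.

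Chemokines, cytokines and their receptors fell more often than they rose, with 29 lower, 6 higher and 2 of 37 not passing (median −1.11, cameraPR adjusted p = 3.33e-14). The median was −2.15 after subtraction of background and −0.62 with no filter. Ccl7, a monocyte attractant, fell 33.6-fold from 14030 ± 1716 to 417 ± 61.1. Cxcl14 fell 26.4-fold from 6648 ± 631, and Pf4 (Cxcl4) fell 23.4-fold from 36027 ± 5615 to 1541 ± 221. Genes of the type I interferon response had 22 of 26 tested members lower, 0 higher and 4 not passing (median −0.80, or −1.60 after subtraction of background, cameraPR adjusted p = 3.18e-05). Oasl2 fell 3.36-fold, and Irf9, a subunit of the factor that transmits interferon signals, fell 2.91-fold. Dhx58, a sensor of viral RNA, fell 2.58-fold and Trim30a fell 2.51-fold. Antigen presentation genes had 8 lower, 1 higher and 5 of 14 not passing, and the shift of the list did not pass (median −0.32, cameraPR adjusted p = 0.0716). With no filter it passed, at a median of −0.16 (cameraPR adjusted p = 0.0445). Its falls included those of the protease cathepsin S (Ctss, 3.62-fold), the co-stimulatory receptor Cd40 (3.56-fold) and H2-DMa (3.09-fold), which loads peptides on class II molecules. Batf3, a transcription factor of dendritic cells, fell at least 1.43-fold.

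Genes of the cell cycle fell together. Of 42 tested, 38 were lower, 0 higher and 4 did not pass (median −0.86, cameraPR adjusted p = 2.44e-06). The G1 cyclins led, with Ccnd1 down 4.62-fold from 18943 ± 1114 to 4102 ± 504 and Ccnd2 down 2.73-fold. The mitotic kinase Pbk fell 2.65-fold and thymidine kinase Tk1 fell 2.51-fold. Cell cycle inhibitors were lower too, with 9 down, 3 up and 3 of 15 not passing (median −0.59, cameraPR adjusted p = 0.0475). That list's adjusted p was 0.131 with the preset correlation raised to 0.05, and its median −0.98 after subtraction of background and −0.24 with no filter. Cdkn1a (p21) fell 3.95-fold, Cdkn2d fell 2.58-fold and the retinoblastoma gene Rb1 fell 2.58-fold, whereas Trp53inp1 rose 2.37-fold.

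Other osteoclast-related lists were divided. Of 19 tested genes of immunoreceptor (ITAM) signalling, which co-stimulates osteoclast formation, 10 fell, 6 rose and 3 did not pass (median −0.41, cameraPR adjusted p = 0.22). With no filter the list passed, although its median was then 0.00 (cameraPR adjusted p = 0.0434). Beside the rise of Oscar, the receptor Trem2 fell 6.24-fold from 21652 ± 779 to 3471 ± 236, Sirpb1a fell 3.99-fold and Clec5a fell 2.87-fold. Among 12 tested factors through which osteoclasts signal to osteoblasts, 6 rose, 4 fell and 2 did not pass (median 0.25, cameraPR adjusted p = 0.298). Their median was −0.02 with no filter and 0.47 with the signal filter. Sphk1, which makes sphingosine 1-phosphate, rose at least 10.9-fold, and the growth factor Pdgfb rose 4.85-fold. The receptor Igf2r rose 3.16-fold. Igf1 fell 13.2-fold from 2838 ± 64.9 to 216 ± 21.4. Genes of the cytoskeleton and podosomes, the adhesion structures of osteoclasts, gave 8 rises, 10 falls and 7 of 25 not passing. Their median was −0.12 and their mean 0.30. The direction given by cameraPR was up, and the shift of the list did not pass (cameraPR adjusted p = 0.0848). With no filter it passed, also as a shift up, although the median was −0.01 (cameraPR adjusted p = 0.0186). The small GTPase Rhou rose 6.25-fold from 198, at the floor, Pstpip1 rose 5.03-fold, vinculin (Vcl) rose 3.10-fold and the tubulin Tubb6 rose 3.08-fold. Cholesterol synthesis genes had 11 falls, 2 rises and 6 of 19 not passing (median −0.34, cameraPR adjusted p = 0.0787), and passed with no filter at a median of −0.25 (cameraPR adjusted p = 0.0052). Stard4, Cyp51 and Dhcr7 fell by 1.46, 1.16 and 0.92 on the log2 scale. Further large rises outside these lists were those of Mt3, a metallothionein (at least 97.1-fold), the actin-severing protein scinderin (Scin, 92.7-fold, 232 ± 22.7 to 21484 ± 3139) and Pde4dip (at least 27.6-fold). Pde4dip has 2 further array genes, which rose 6.16-fold and at least 1.34-fold.

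Markers of other cell types were mostly at background. In the B cell list 1 of 14 genes was tested, Cd79b, which fell from 286 ± 7.64 to 205 ± 21.3. In the T and NK cell list 3 were tested. Prf1 rose 1.57-fold, Cd8b1 fell from 2606 ± 322 to 2031 ± 141, and the third did not pass (median −0.22, mean 0.02, cameraPR adjusted p = 0.929). The list's median was 0.22 with the signal filter, −0.03 with no filter and −0.37 after subtraction of background. Granulocyte genes were detected in both cultures. Of 13 tested, S100a8 fell from 6265 ± 845 to 4648 ± 611 and S100a9 from 1929 ± 147 to 1420 ± 233, while 11 did not pass (median −0.31, cameraPR adjusted p = 0.452). In the erythroid list 2 genes were tested, and Epor rose at least 1.02-fold. In the megakaryocyte and platelet list 2 rose and 3 fell, with a median of −0.68 (−0.25 with undetected groups at the floor, 0.01 with no filter and −2.46 after subtraction of background), a mean of 0.28 and a cameraPR adjusted p of 0.273. F2r, the thrombin receptor, rose at least 142-fold to 28037 ± 662, whereas Treml1 fell at least 2.26-fold and Ppbp at least 1.19-fold. This list shares Itgb3 with the resorption list and Pf4 with the chemokine list. Of the mast cell list only Gata2 was tested, which rose at least 2.81-fold to 556 ± 51.9. It also stands in the progenitor list, where Tal1 (1.84-fold), Ly6a (1.76-fold) and Cd34 (at least 1.39-fold) fell (median −0.69, −0.12 with no filter and −1.21 after subtraction of background, cameraPR adjusted p = 0.817). Of 3 tested stromal genes, fibronectin (Fn1) fell 5.65-fold from 1736 ± 270, and the other 2 did not pass (median −0.08, 0.00 with no filter and −0.26 after subtraction of background, cameraPR adjusted p = 0.283).

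Reference and stress genes had medians near 0, with means further from it. Of 14 tested housekeeping genes 9 did not pass, 3 rose and 2 fell (median 0.06, mean 0.29, cameraPR adjusted p = 0.281). The transferrin receptor Tfrc rose 5.11-fold from 6168 ± 610 to 31519 ± 3150, Rplp0 rose 2.02-fold and Rpl13a 1.99-fold, and Hprt fell 1.96-fold. Heat shock and stress genes gave 4 rises, 4 falls and 9 of 17 not passing (median −0.06, mean −0.32, cameraPR adjusted p = 0.244). Atf3 fell 11.7-fold from 2443 ± 199 to 208 ± 15.5, the haem-degrading enzyme Hmox1 fell 9.95-fold from 14721 ± 1944, and the glutathione synthesis gene Gclm fell 2.63-fold. The mitochondrial chaperonin Hspe1 rose 2.74-fold.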

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

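All tests in this part were chosen after the result was seen. The detection p kept 1149 array genes out of the test although their mean lay above the lowest signal at which stepped detection p-values mark a gene as detected, 198 with M-CSF alone or 196 with RANKL. They stood out as signal in data that the comparison did not use. Tested in limma with that signal floor in place of the detection p, 58 of them were, by the measured signals, at least 2-fold higher with RANKL and 52 at least 2-fold lower. Among the former are Car2, carbonic anhydrase 2, which supplies protons for resorption, at 132 ± 2.37 and 1341 ± 370 (adjusted p = 4.55e-09, limma), Src, a kinase that resorbing osteoclasts need, at 161 and 902 (adjusted p = 1.02e-09, limma), and Calcr (adjusted p = 3.6e-06, limma). Among the latter are the endocytic adaptor Dab2, at 27687 ± 2208 and 2424 ± 227 (log2 −3.51), Ms4a7, at 6590 ± 808 and 533 ± 52.0 (log2 −3.63), and the proliferation marker Mki67, at 3262 ± 725 and 1279 ± 180 (log2 −1.35). Of the 1149, 2 had stepped detection p-values in both groups.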

How the results depend on the processing

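The signal filter, doubled SDs and background subtraction were chosen after seeing the data. Over the 13 alternatives, the count of changed genes stayed within 1.5 times of 6369 except for 3868 on the linear scale without moderation and 3054 with doubled SDs. The count at 2-fold stayed within 1.5 times of 1532 except for 2759 after background subtraction, where smaller denominators give larger folds. Some alternatives could hardly move these counts. The series' value table holds the same means. The median log2 fold removed by centring was −0.0025, and quantile normalization shifted the median by 0.00028. The fit without an intensity trend and the moderated fit on the linear scale leave the folds unchanged. The share of higher calls stayed within 10 percentage points throughout. Of 105 tested genes under the naming rule, 95 kept their direction and side of the threshold under all 8 settings that apply to them, and 10 lost their call with doubled SDs only (Itgb3, Tnfrsf11a, Cd79b, Cd8b1, S100a8, S100a9, Epor, Ppbp, Ly6a and Cd34). The naming rule favours genes with large changes, so the stability of these 95 genes partly restates that choice. Among the lists, cell cycle inhibitors lost their call at a preset correlation of 0.05 (adjusted p = 0.131). With no filter, 4 further lists passed in cameraPR, although their medians were smaller in size than with the filter. ITAM signalling (adjusted p = 0.0434), antigen presentation (0.0445) and cholesterol synthesis (0.0052) passed as shifts down, and cytoskeleton (0.0186) as a shift up. The comparison in cameraPR is with the other genes fitted, which with no filter include those detected in neither group. These passes therefore do not show larger shifts, and their cause was not tested. For the megakaryocyte list the direction given by cameraPR turned from up to down after background subtraction (median −2.46, adjusted p = 0.65), with members going both ways. No replicate could be left out and no other split of the arrays tried, since the files hold group means. No paired analysis was possible because the files hold group means only and do not say whether the replicates of the 2 groups were matched. Signal over background limits genes under about 198, where folds are compressed. Some folds with a dimmer group above 198 are compressed too. After background subtraction the fold of Ctsk, at 302 with M-CSF alone, was 1.92 times larger. That of Id1, at 328 with RANKL, was 1.73 times larger.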

Other observations

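The gene groups and tests in this part were chosen after the data were seen. A group of receptors, bridging molecules and other genes linked to the uptake of dying cells and debris was mostly lower with RANKL. Of 24 tested genes, 22 were lower and 2 higher (median −2.21, cameraPR adjusted p = 1.28e-33). The group holds several of the largest falls named above, Fcrls and the C1q genes, so this p partly restates how it was chosen. Of the 24, some also stand in the macrophage list, among them the C1q genes, Mrc1 and Mertk. Others do not, such as Gas6, a bridging ligand, from 8176 to 429, the scavenger receptor Stab1, from 9970 to 462, and Itgb5, an integrin chain, from 14660 to 1189. Mfge8, another bridging protein, rose from 2291 to 7978, and the scavenger receptor Scarf1 rose from 324 to 1681. Toll-like receptors and their adaptors had 16 of 22 tested genes lower and 0 higher (median −1.46, cameraPR adjusted p = 7.39e-11). Tlr13 went from 7054 to 606 and Tlr7 from 4267 to 389, whereas the adaptor Myd88 fell from 5859 to 4949, and the kinase Irak4, at 519 and 461, did not pass. This group shares Cd14, Cd180, Ly86, Tlr2, Tlr4, Tlr7 and Tlr8 with the macrophage list.

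Mitochondrial ribosomal proteins and import factors rose with the respiratory chain, 47 of 55 tested higher and 0 lower (median 0.65, cameraPR adjusted p = 1.04e-06). Cytosolic ribosomal proteins had 19 of 68 higher, 0 lower and 49 not passing (median 0.11, cameraPR adjusted p = 0.163). Of the 49, 12 lay above 85% of the highest signal in both groups, where a change is hard to see. Genes of iron and haem handling went both ways, with 10 higher, 8 lower and 10 not passing (median 0.05, cameraPR adjusted p = 0.474). From the share over all tested genes, 8.14 higher and 8.22 lower would be expected, so the list as a whole shows no shift. Its members named here were picked after their values were seen. Rises included those of Tfrc, the iron importer Slc11a2, from 468 to 1394, the ferritin receptor Ncoa4, from 558 to 2336, and Bdh2, from 1757 to 38459. The iron exporter Slc40a1 fell from 2111 to 691, the phagosomal metal transporter Slc11a1 from 25898 to 6792, and Hfe from 1329 to 258. Slc25a37 fell from 1792 to 862 and Slc48a1 from 8075 to 4086. The ferritin chain Ftl1, at 34419 and 34494, did not pass.

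The V-ATPase subunits rose by a median of 1.23, and a general rise of lysosomal genes could account for this. For this, lysosomal hydrolases and membrane proteins had to rise by a median of at least 0.61, a limit set after seeing the data. Their median was −0.29 (quartiles −1.20 and 0.26), with 11 of 41 tested genes higher, 21 lower and 9 not passing (cameraPR adjusted p = 0.00887, down, and 0.0898 with the preset correlation raised to 0.05). Falls included Lgmn, from 34903 to 3972, Lamp1, from 29395 to 8428, and Ctsc, from 22758 to 4132, and rises included Arsb, from 6525 to 28491, and Smpd1, from 918 to 5722. For the listed genes these values argue against a general rise. The list was also drawn up after seeing the data, and it leaves out the enzymes Ctsk and Acp5, which rose. A change specific to the pump and some hydrolases remains a hypothesis.

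The numbers of genes higher and lower were nearly equal, 3179 and 3190. A candidate explanation is that the authors' normalization gave the arrays a common distribution of signals. The sorted log2 signals of the 2 groups differed by a median of 0.010 over the detected range, against a median absolute log2 fold of 0.33 over the tested genes, which is consistent with such a step. A group difference in the total amount of RNA per cell would then not show in the table. No biological explanation was tested.

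Macrophage transcripts that remained with RANKL may come from cells that the cytokine left unchanged. As their only source, such cells would leave the same share of each transcript. Over 22 genes of the macrophage list with a signal above 2000 in the control, the share left after subtraction of background ran from at most 1.10% for C1qa, not detected with RANKL, to 105% for Lyz1 (67.4% for its close paralog Lyz2), with a median of 15.8%. Its upper quartile was 10.7 times the lower, 47.2% against 4.43% (9.25 times over the 21 genes detected in both groups), so unchanged cells alone do not account for the pattern. Unequal regulation within the responding cells stays open as the biological explanation, and a small share of unchanged cells beside it is not excluded.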
